A study of Drosophila melanogaster with 16 samples.

How the data were processed

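RNA was measured in pools of 50 hand-sorted Drosophila melanogaster embryos, per the labels' protocols. Flies laid eggs for 1 h, and the embryos were aged for another 2 h at 25 °C. Libraries were made from total RNA with a stranded kit, and there were 16 of them, from 4 genotypes at 2 stages with 2 replicates each. The stages were nuclear cycle 14 (NC14, stage 5) and stages 7 to 8 (St7-8). The genotypes were the control wm4h, the Jasper alleles Su113 and Su140, and an allele of Su(var)3-9, each named here as in the labels.

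The values used were whole-number counts per gene, deposited by the authors as 1 table without normalization. The genome build dm6 and the package DESeq2 were named in the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation release were not given in the sources used here. The table held 17753 genes by FlyBase identifier. Symbols and dm6 coordinates came from Ensembl release 115, which matched 17626 identifiers. The other 127 held 1.06% of the counts, and 1532 genes had a count of 0 in all libraries.

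Total counts were 43466130 to 92790237 per library, and the 10 most abundant genes took 4.41 to 5.72% of them. CPM is the edgeR unit of counts scaled by library size after TMM, and the floor set by 3 counts lay between 0.0299 and 0.0573 CPM per library. This floor covers counting error alone, because reads without molecular identifiers are not independent molecules.

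Everything else was computed for this account with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Tables and figures were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Genes were kept by filterByExpr with the 8 groups, which left 12398 tested and 5355 removed. Libraries were scaled by TMM, and 1 quasi-likelihood model of edgeR (glmQLFit, glmQLFTest) with 8 group means was fitted to all 16 libraries. Its residual degrees of freedom were 8 and its common biological coefficient of variation was 0.4. Each contrast of group means was tested two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The adjusted p of a gene is from this model unless another tool is named. Log2 CPM used a prior count of 2. Changes are log2 fold changes with the standard error (SE) of the model, and levels are mean CPM ± SD over 2 libraries. Where all libraries of a group had 0 counts, the fold was computed against 3 counts per library and is written as a lower bound. Where a group's highest count lay between 1 and the floor, the ratio is given with its counting interval. The p-values measure the spread between these samples, each a pool of 50 embryos, and this spread may be technical in part. All 8 groups shared 1 estimate of the spread per gene. Replicates differed more at St7-8 (SD of the log2 CPM difference 0.92 to 1.55) than at NC14 (0.57 to 0.85). At St7-8 the p-values thus rest on a smaller spread than its own replicates show.

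The comparisons, the gene lists, the rule for named genes and, with 2 exceptions named with them, the alternatives were chosen before the data were examined. In each mutant comparison the rule named Jasper, Su(var)3-9, JIL-1 and w. It named the 6 genes with the highest and the 6 with the lowest log2 fold change among those past the threshold, with a mean of at least 2 CPM over the 4 libraries and both mutant libraries on the same side of both controls. It also named up to 3 genes of each list by adjusted p, and the 8 genes with the smallest larger adjusted p in both Jasper alleles. For the other contrasts it named 5 genes each way. The text prints part of the genes so named.

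There were 40 lists. They comprised gap, pair-rule, segment polarity, Hox, dorsal ectoderm and amnioserosa, mesoderm, neural, Enhancer of split, endoderm and haemocyte, cellularization and gastrulation, X-counting, dosage compensation, maternal germ plasm and meiosis, piRNA pathway, JASPer and interband chromatin, heterochromatin protein, chromosome 4, pericentromeric, w-flanking, histone, ribosomal protein, small nuclear and nucleolar RNA, cytochrome P450 and glutathione S-transferase, and heat shock genes, and markers of older embryos and of ovary and adult tissue. The others were the genes of each chromosome arm, pericentromeric genes by position, and genes within 500 kb of w, of Jasper and of Su(var)3-9. Lists of immune genes with 4 tested members, of histone genes with 4, and of mitochondrial genome genes and transposable elements with 0 fell under the minimum of 5 members for a list test. The other 36 lists were tested with camera on voom values, with a preset correlation of 0.01 between genes, adjusted over the 216 pairs of a list and a mutant comparison. Each test was repeated with an estimated correlation. Fisher's exact test, two-sided, compared the direction of the genes past the threshold between each chromosome arm and the rest, and was chosen after the data were seen. It takes genes as independent, which they are not, so its p-values do not measure the spread between samples. The arm shares were not recomputed with a library left out. The fry test, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, gave adjusted p values of 0.106 or more for the lists past camera.

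Alternatives were relative log expression (RLE) size factors, no filter on low counts, a block for the replicate number, the DESeq2 Wald test, a fit to the libraries compared or to those of the same stage alone, and the omission of each library in turn. With 1 library of a group left, that library was assumed to vary like the others. Another 2 alternatives, the exceptions, were chosen after the data were seen. One left out the second St7-8 libraries of Su113, Su140 and wm4h together, and the other added a later-zygotic score as a covariate, the mean log2 CPM of the segment polarity and Hox lists in each library. Across genes, which are not independent replicates, the deviations of libraries with the same replicate number had r of -0.5 to 0.33 between groups, both at St7-8 (wm4h with Su140, and Su113 with Su140). The deviations thus had no common sign, and the numbers were not taken as pairs.

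The scripts were tested on counts simulated from the means and library sizes of these samples, with 12263 genes in each step. In the simulated Su113 comparison at NC14, 40% of genes changed by 1 on the log2 scale and 78% of those changed by 2 were recovered, and 5 of 123 calls were false. In the simulated Su113 comparison at St7-8, 32% and 83% were recovered, and 2 of 117 calls were false. Each gene had the same spread in all simulated groups. In the samples, the SD of the replicate difference was 1.34 in Su113 and 1.55 in Su140 at St7-8, against 0.57 and 0.74 at NC14. The simulated rate of false calls may therefore be too low for St7-8. In a simulated list test at NC14 for Su140, with 12398 genes and 100 lists, the shifted list had an adjusted p of 6.43e-17 and 0 other lists passed. The simulated genes varied independently and the lists were random, so this does not give the rate of false calls for lists of correlated genes. Correlations of log2 fold changes between mutants were also simulated, in 20 runs without any effect, because all mutants of a stage share the same 2 control libraries.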

Results

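The data were RNA counts of 16 libraries of Drosophila melanogaster embryos, from 4 genotypes at NC14 and at St7-8, with 2 libraries in each of the 8 groups. The series concerns JASPer, a transcriptional cofactor whose PWWP domain binds a methylated histone mark, and the suppression of position effect variegation. The control wm4h carries an X chromosome inversion that places the eye pigment gene w next to heterochromatin, where its activity varies from cell to cell. Su113 and Su140 are alleles of Jasper, and Su(var)3-9 encodes a histone methyltransferase of heterochromatin. Total counts at NC14 were 59662040 and 91678951 in wm4h, 89559757 and 75098459 in Su113, 67579862 and 84322487 in Su140, and 74997916 and 92790237 in Su(var)3-9. At St7-8 they were 70635572 and 82871567 in wm4h, 88185406 and 43466130 in Su113, 73392895 and 65918287 in Su140, and 63890281 and 81611151 in Su(var)3-9.

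Jasper, Su(var)3-9, JIL-1 and w were examined first in each group, each with n = 2. Jasper (FBgn0039743, 3R from 30052514 to 30054697) stood at 141 ± 22.2 CPM in wm4h at NC14, 156 ± 7.11 in Su113, 150 ± 12.5 in Su140 and 166 ± 5.62 in Su(var)3-9. At St7-8 the values were 159 ± 12.2, 113 ± 20.3, 137 ± 13.3 and 147 ± 24.2 CPM. Su(var)3-9 (FBgn0263755, 3R from 15259864 to 15263458) stood at 111 ± 14.1, 130 ± 0.319, 83.7 ± 7.74 and 130 ± 22.4 CPM in the same order at NC14. It stood at 115 ± 30.4, 82.4 ± 27.6, 109 ± 6.8 and 153 ± 19.3 CPM at St7-8. Neither gene passed the test in any of the 6 mutant comparisons, with adjusted p of 0.129 or more by edgeR. Without Su113 replicate 1, Su(var)3-9 in Su113 at St7-8 reached an adjusted p of 0.0499. These levels do not check the genotype labels, since the lesions themselves are not visible in counts per gene. Su(var)3-9 also shares its span and strand with eIF2gamma. JIL-1 (FBgn0020412, 3L from 11078752 to 11093193), the kinase that acts with JASPer, stood at 346 ± 13.8 CPM in wm4h at NC14, 269 ± 2.63 in Su113, 427 ± 63.3 in Su140 and 243 ± 63.9 in Su(var)3-9. None of these passed the test (adjusted p of 0.354 or more). At St7-8 it fell from 326 ± 114 CPM in wm4h to 157 ± 12.1 in Su(var)3-9 (log2 fold change -1.06 ± 0.24, adjusted p = 0.00864), against 248 ± 22.9 in Su113 and 272 ± 46.1 in Su140. That call ended without wm4h St7-8 replicate 2 (-0.65, adjusted p = 0.114) and without Su(var)3-9 St7-8 replicate 2 (-0.98, adjusted p = 0.0655). It also ended without the second St7-8 libraries (-0.66, adjusted p = 0.0661) and with the later-zygotic score as a covariate (-0.44, adjusted p = 0.537).

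The gene w (FBgn0003996, X from 2790599 to 2796466) was higher in both Jasper alleles at both stages, and in each case both mutant libraries lay above both control libraries. At NC14 it rose from 0.344 ± 0.108 CPM in wm4h to 4.64 ± 1.26 in Su113 (log2 fold change 3.76 ± 0.52, adjusted p = 0.00815) and to 9.25 ± 1.52 in Su140 (4.75 ± 0.55, adjusted p = 0.000738). At St7-8 it rose from 0.49 ± 0.0942 CPM to 2.7 ± 1.54 in Su113 (2.46 ± 0.49, adjusted p = 0.0253) and to 5.24 ± 2.14 in Su140 (3.41 ± 0.51, adjusted p = 0.00998). In the Su(var)3-9 mutant w stood at 0.126 ± 0.0196 CPM at NC14 (-1.43 ± 0.52, adjusted p = 0.247) and at 0.266 ± 0.024 at St7-8 (-0.88 ± 0.49, adjusted p = 0.216). The cell adhesion gene kirre (X from 2740384 to 3134532), whose span covers w on the opposite strand, rose with it at NC14. It went from 1.87 ± 0.27 CPM to 12.7 ± 2.48 in Su113 (2.76 ± 0.55, adjusted p = 0.0433) and to 32.1 ± 1.88 in Su140 (4.1 ± 0.58, adjusted p = 0.0028). At St7-8 it did not pass in Su113 (1.69 ± 0.53, adjusted p = 0.101) and passed in Su140 (2.66 ± 0.54, adjusted p = 0.0419). That call ended without wm4h replicate 1 (2.77, adjusted p = 0.0734), wm4h replicate 2 (2.55, 0.335), Su140 replicate 2 (2.44, 0.165) or the second St7-8 libraries (2.39, 0.315). It also ended with the block (2.68, 0.0612), with the later-zygotic score (2.1, 0.216) and in the fit to St7-8 libraries alone (2.75, 0.28), while the fold change stayed positive. Because the span of kirre covers w, the assignment of reads between them is uncertain. Their neighbours in dm6, rst (0.37 ± 0.31 in Su113, 0.49 ± 0.31 in Su140) and N (0.26 ± 0.15 and 0.25 ± 0.15), did not pass at NC14. The inversion of wm4h can change this order, and whether the mutants carry the same inversion was not tested. Of the other genes plotted around w, those past the threshold in Su140 at NC14, named after their values were seen, were eIF2Bbeta (0.8 ± 0.2, adjusted p = 0.0291), CG2701 (0.55 ± 0.15, adjusted p = 0.0391) and ttm50 (-0.99 ± 0.24, adjusted p = 0.0281). The difference between the alleles did not pass for w at NC14 (-1 ± 0.46 for Su113 against Su140, adjusted p = 0.234). Its change of effect between stages did not pass either (-1.29 ± 0.67 in Su113, adjusted p = 0.33, and -1.34 ± 0.67 in Su140, adjusted p = 0.218). The call of w in Su140 at NC14 held with each library left out (4.45 to 5.07). That in Su113 ended without Su113 NC14 replicate 1 (3.44, adjusted p = 0.0862). At St7-8 the calls of w ended without wm4h replicate 1 (2.28, adjusted p = 0.0732 in Su113 and 3.23, 0.0533 in Su140), wm4h replicate 2 (2.67, 0.149 and 3.62, 0.101) or, in Su140, Su140 replicate 2 (2.92, 0.0513). They also ended in the fit to the St7-8 libraries alone (2.62, 0.189 and 3.52, 0.216), and in Su140 with the later-zygotic score as a covariate (2.99, adjusted p = 0.0938). In Su113 at St7-8 the log2 fold change of w was 1.71 without Su113 replicate 1 (adjusted p = 0.0411) and 3.11 without Su113 replicate 2 (0.0171). The call of kirre in Su113 at NC14 ended without any 1 of the 4 libraries compared, with a fold change of 2.54 to 2.95 and an adjusted p of up to 0.287, and with the block (2.76, 0.0643). That in Su140 at NC14 held with each library left out and ended with the later-zygotic score (5.06, adjusted p = 0.0586).

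**Figure D1:**
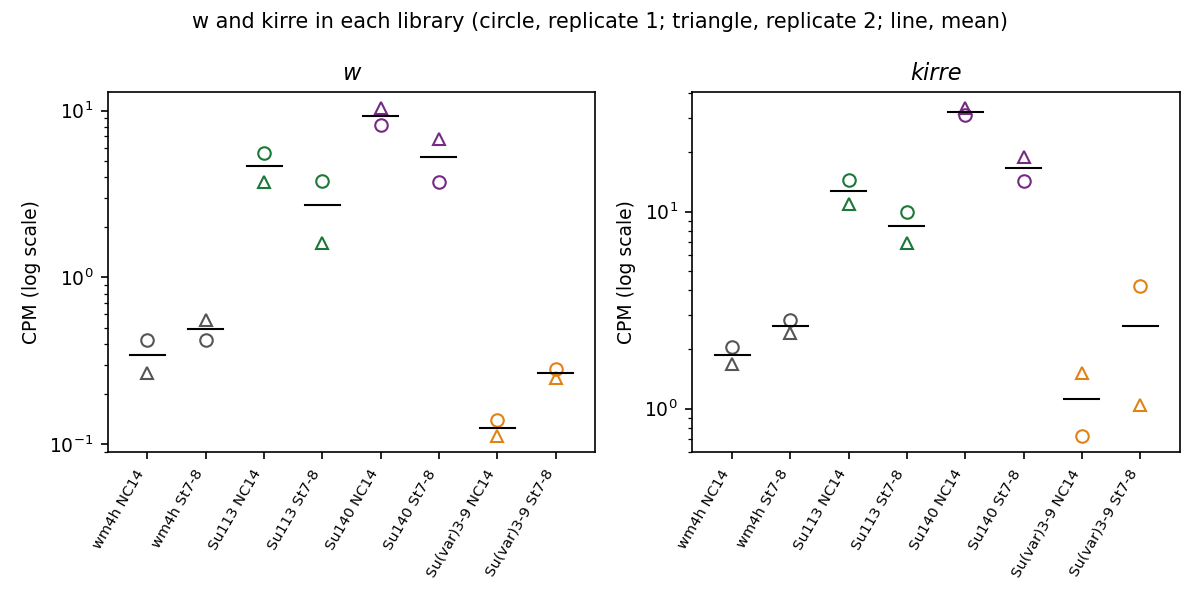
Levels of w and kirre in CPM (log axis) in each of the 16 libraries, with a circle for replicate 1, a triangle for replicate 2 and a line at each group mean. Both genes lie higher in Su113 and Su140 than in wm4h at NC14, where w is at 0.42 and 0.268 in the 2 wm4h libraries.

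**Figure D2:**
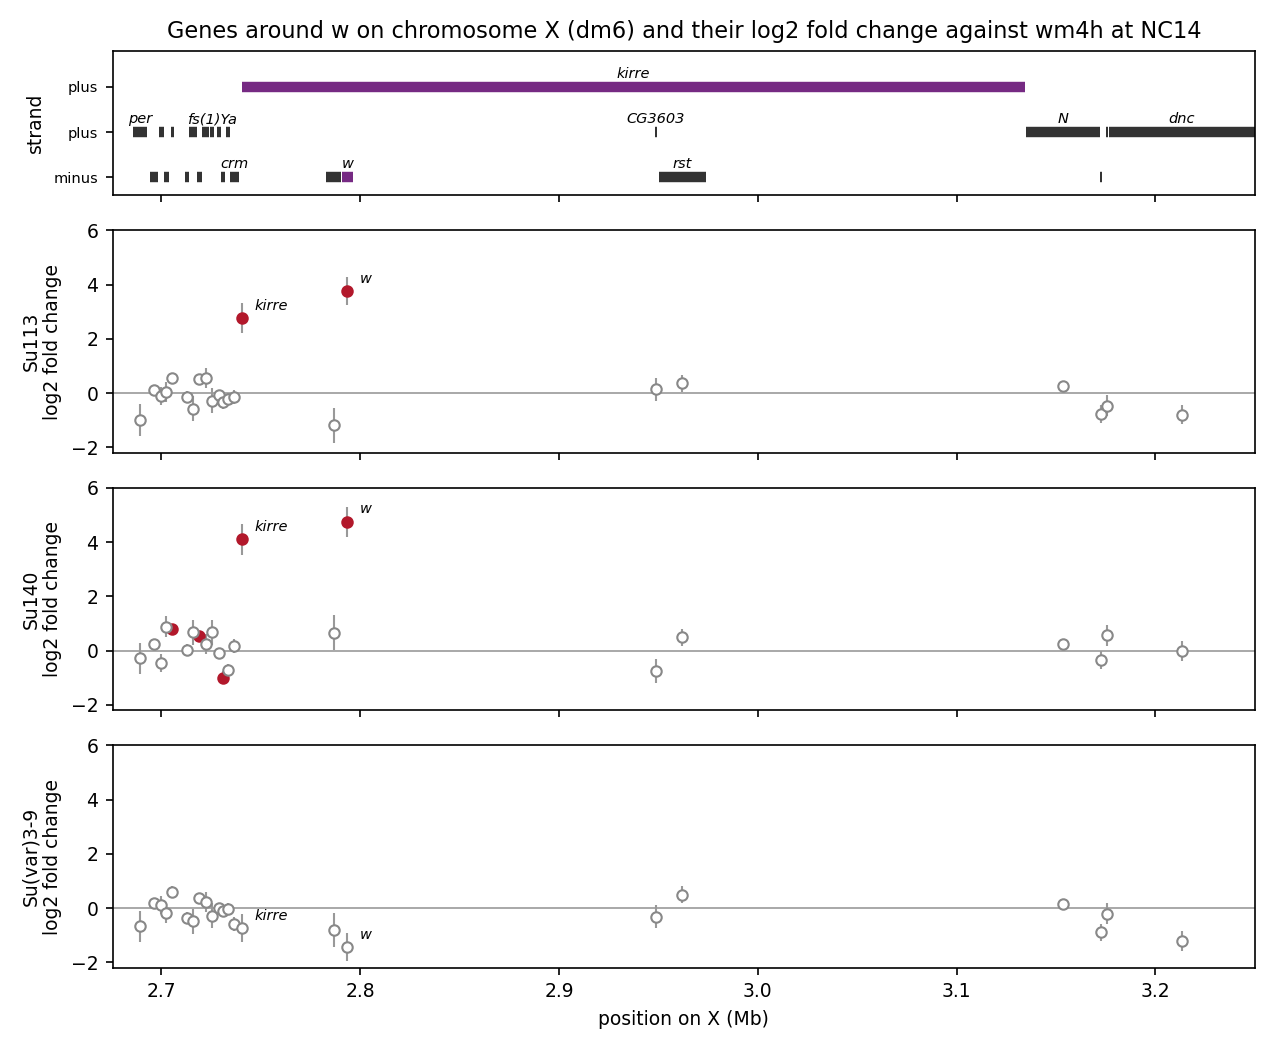
Log2 fold change against wm4h at NC14, with its standard error, of the genes around w on the X chromosome (dm6), in Su113, Su140 and Su(var)3-9, plotted at their positions with kirre at its start. Filled red points have an adjusted p under 0.05, among them w and kirre in both Jasper alleles.

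The number of genes past the threshold differed widely between comparisons. Against wm4h at NC14 it was 116 in Su113 (47 higher, 69 lower), 1185 in Su140 (375 higher, 810 lower) and 41 in Su(var)3-9 (18 higher, 23 lower). At St7-8 it was 353 in Su113 (229 higher, 124 lower), 143 in Su140 (47 higher, 96 lower) and 3080 in Su(var)3-9 (1108 higher, 1972 lower). Most had changed at least 2-fold, with 103, 825 and 37 genes at NC14 and 298, 129 and 1984 at St7-8. In the 3 NC14 comparisons 1762, 3384 and 1790 genes had an unadjusted p under 0.05, and in those at St7-8 there were 3166, 2273 and 4588, where 620 are expected by chance.

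**Figure D3:**
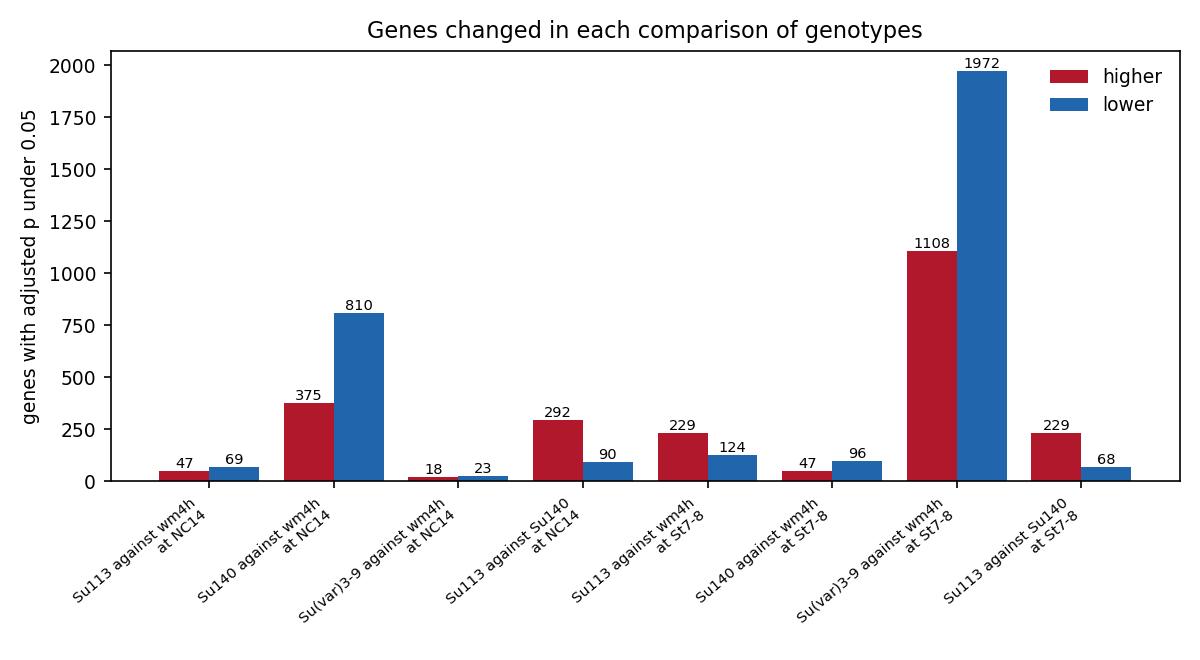
Number of genes higher and lower at an adjusted p under 0.05 in the 6 comparisons of a mutant with wm4h and the 2 comparisons of Su113 with Su140. The bars are highest for Su(var)3-9 at St7-8 (3080 genes) and Su140 at NC14 (1185 genes).

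In Su113 at NC14, the genes with the largest falls were each lower in both mutant libraries than in both controls. Arc1, a capsid-like protein of neurons, fell from 207 ± 19.2 to 3.17 ± 0.982 CPM (log2 fold change -6.02 ± 0.86, adjusted p = 0.00923). The cell adhesion gene Dscam2 fell from 82.2 ± 11.7 to 3.29 ± 0.361 (-4.64 ± 0.41, adjusted p = 0.000298). Tsp26A, a tetraspanin, fell from 45.1 ± 3.88 to 9.12 ± 0.495 CPM (-2.31 ± 0.20, adjusted p = 0.000286). The spliceosomal RNA gene snRNA:U2:34ABa fell with the smallest adjusted p (-6.18 ± 0.39, adjusted p = 3.21e-05), but it belongs to a multi-copy family in which reads are hard to assign. The intraflagellar transport gene Oseg5 had at most 2 counts in Su113, a ratio of 363 (100 to 3000) below wm4h. Among genes that rose were spn-E, a helicase of the piRNA pathway, from 127 ± 18.3 to 325 ± 2.29 CPM (1.35 ± 0.20, adjusted p = 0.00933). Others that rose were Smyd4-1 (1.55 ± 0.17, adjusted p = 0.00227), the peroxisomal import gene Pex19 (1.07 ± 0.13, adjusted p = 0.00384), and Rab26 (5.92 ± 1.14, adjusted p = 0.0367). Of 108 cytochrome P450 and glutathione S-transferase genes, 2 rose and 4 fell, among them Cyp6d4 (-3.27 ± 0.41) and Cyp6a13 (-3.73 ± 0.59). The counts were 5 and 10 when adjusted over the list alone (camera adjusted p = 0.933). The developmental lists held 1 gene past the threshold, the segment polarity gene mid (-2.53 ± 0.50, adjusted p = 0.0424). Adjusted over the list alone, 4 of 9 segment polarity genes were lower, 1 of 8 Hox genes was higher and 3 lower, and 3 of 11 Enhancer of split genes and 1 of 9 mesoderm genes were lower.

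By camera, lists lower in Su113 at NC14 were pair-rule (median log2 fold change -0.50, adjusted p = 0.0161), segment polarity (-1.37, adjusted p = 0.0246), mesoderm (-0.84, adjusted p = 0.00972) and Enhancer of split genes (-0.82, adjusted p = 0.0342). Each had adjusted p = 0.83 with an estimated correlation. Ribosomal protein genes (median 0.23, adjusted p = 0.000272) and the pericentromeric gene list (0.15, adjusted p = 0.0281) were higher by camera with 0 members past the edgeR test. They likewise had adjusted p = 0.83 with an estimated correlation. Leaving out a library changed the count of 116 genes to 39 (wm4h replicate 1), 272 (wm4h replicate 2), 6 (Su113 replicate 1) or 14 (Su113 replicate 2). Of the 34 named genes past the threshold, the 6 whose calls held with each of these libraries left out were snRNA:U2:34ABa, Dscam2, CG6567, pyd3, Tsp26A and Smyd4-1.

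In Su140 at NC14, part of the genes that pattern the embryo along its axes after the onset of zygotic transcription fell. Of 8 Hox genes, which set segment identity, 7 fell. Antp went from 120 ± 40 to 18.6 ± 2.31 CPM (log2 fold change -2.68 ± 0.45, adjusted p = 0.00635), and Abd-B from 27.6 ± 2.35 to 4.7 ± 0.385 (-2.55 ± 0.37, adjusted p = 0.00301). Of 9 segment polarity genes 6 fell, among them mid (-3.29 ± 0.52), gsb (-3.31 ± 0.56) and hh (-2.96 ± 0.48), which encodes the Hedgehog signal. Of 9 pair-rule genes 4 fell, with opa going from 879 ± 93.7 to 278 ± 64.3 CPM (-1.66 ± 0.39, adjusted p = 0.0229). Other members that fell were 7 of 17 neural genes (ind at -2.75 ± 0.50) and 7 of 16 dorsal ectoderm and amnioserosa genes (peb at -2.68 ± 0.45). So did 3 of 11 Enhancer of split genes (E(spl)m5-HLH at -2.78 ± 0.44) and 2 of 9 mesoderm genes (htl, a fibroblast growth factor receptor, at -1.82 ± 0.42). The others were 2 of 8 endoderm and haemocyte genes (srp at -1.78 ± 0.42), 3 of 10 cellularization and gastrulation genes (Toll-6 at -2.69 ± 0.59) and 1 of 7 gap genes (knrl at -1.58 ± 0.39). No member of these lists rose past the test over all genes. Adjusted over the list alone, 7 Hox, 7 segment polarity, 7 pair-rule, 8 neural, 8 dorsal ectoderm, 6 Enhancer of split, 3 mesoderm, 5 endoderm, 3 cellularization and 1 gap gene were lower. There were 2 dorsal ectoderm, 1 neural and 1 Enhancer of split gene that were higher. Of these lists, those past camera with the smallest adjusted p were pair-rule (0.000272), Hox (0.000508) and segment polarity (0.00253). The mesoderm, neural, endoderm, dorsal ectoderm and Enhancer of split lists had 0.0107 to 0.0315. All 8 had adjusted p = 0.83 with an estimated correlation. Cellularization genes did not pass camera (adjusted p = 0.357).

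**Figure D4:**
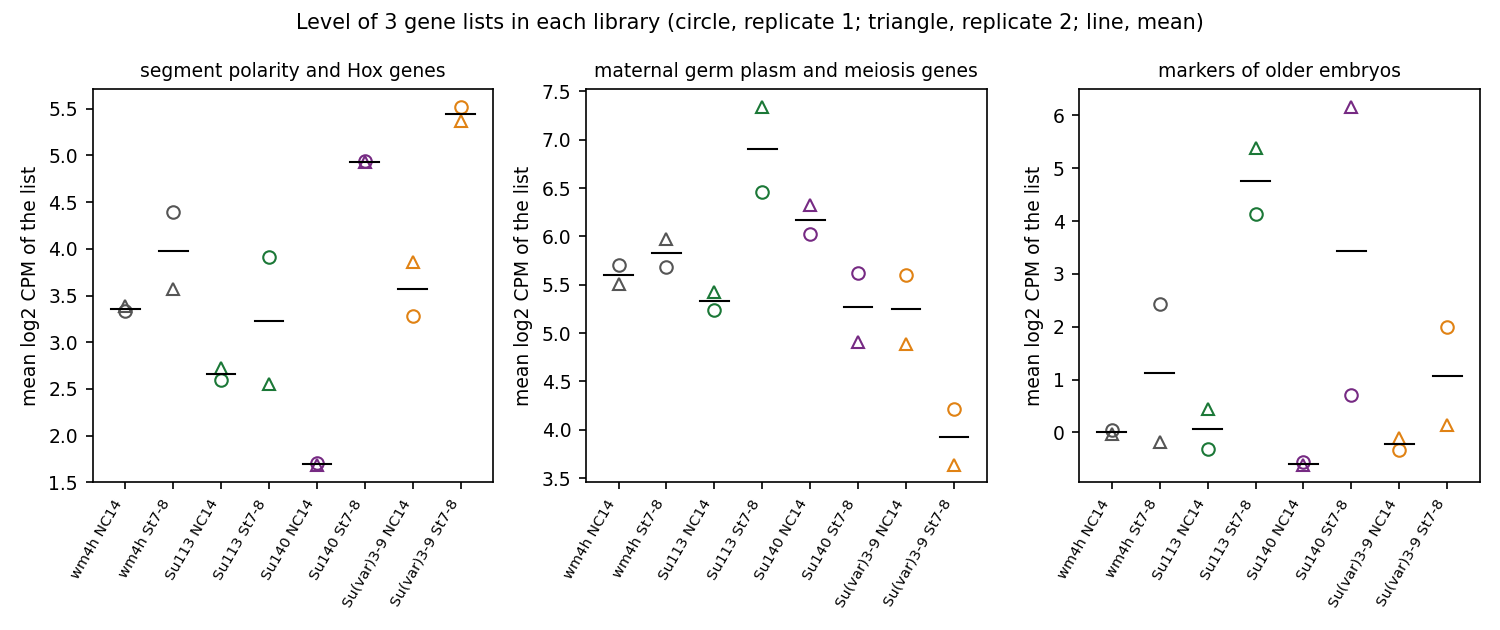
Mean log2 CPM of 3 gene lists in each of the 16 libraries, with a circle for replicate 1, a triangle for replicate 2 and a line at each group mean. Segment polarity and Hox genes are lowest in the Su140 NC14 libraries, and markers of older embryos are highest in Su140 St7-8 replicate 2 at 6.16, against 0.7 in replicate 1.

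Other genes of Su140 at NC14 included some that were silent or nearly so. The receptor gene mthl8 had 0 counts in both Su140 libraries and 12.5 ± 0.927 CPM in wm4h, at least 268-fold lower (adjusted p = 0.00069). Dscam2 (-5.84 ± 0.43), tbc (-5.23 ± 0.44), CG6567 (-3.61 ± 0.28), Tsp26A (-2.89 ± 0.20) and snRNA:U2:34ABa (-6.13 ± 0.39) fell. CCHa1-R, a neuropeptide receptor, rose from 0.0722 ± 0.0331 to 28 ± 26 CPM (8.63 ± 1.51, adjusted p = 0.00783). The piRNA genes spn-E (1.56 ± 0.20) and aub (0.91 ± 0.19, adjusted p = 0.0138) rose, as 2 of 25 in that list with 0 lower (2 and 1 adjusted over the list alone). In turn aub was the 1 gene of 16 in the maternal germ plasm list past the threshold. Both lists were higher by camera (adjusted p = 0.0319 and 0.0142), with adjusted p = 0.83 with an estimated correlation. Of 53 chromosome 4 genes 2 rose and 8 fell, with 3 and 11 adjusted over the list alone (camera adjusted p = 0.154). Among those that fell were mav (-1.86 ± 0.22) and mGluR (-1.62 ± 0.23). Of 23 pericentromeric genes 2 rose, uex (0.80 ± 0.20) and Parp1 (0.52 ± 0.12). In that list 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00366, and adjusted p = 0.83 with an estimated correlation). None of the 14 heterochromatin protein genes or the 12 JASPer and interband chromatin genes passed edgeR's test, over all genes or adjusted over the list alone. The fall of 28SrRNA-Psi:CR40596, a ribosomal RNA pseudogene, from 89.1 ± 123 to 1.34 ± 0.00759 CPM rested on wm4h replicate 1 (-6.05, and -0.46 without it). The count of 1185 became 312 without wm4h replicate 1, 782 without wm4h replicate 2, 124 without Su140 replicate 1, and 150 without Su140 replicate 2. It became 23 with the later-zygotic score as a covariate. Of 85 named genes past the threshold, 31 kept their call with each library left out, among them mthl8, Dscam2, tbc, CG6567, Tsp26A, spn-E, mav, mGluR, kirre and w, and 13 kept it under every alternative run. CCHa1-R, aub, uex, Parp1 and the members of the developmental lists named here, such as Antp, Abd-B, mid, gsb, hh and opa, did not.

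In Su(var)3-9 at NC14, 41 genes passed, and the members of the developmental lists were not among them. The longevity-associated receptor gene mth fell from 12.1 ± 0.359 to 0.811 ± 0.0385 CPM (log2 fold change -3.90 ± 0.44, adjusted p = 0.00341). CanB, a calcineurin subunit (-3.54 ± 0.39, adjusted p = 0.00341), Dscam2 (-3.18 ± 0.38, adjusted p = 0.00504) and the DNA repair gene Ogg1 (-1.72 ± 0.21, adjusted p = 0.0067) fell. The glycolytic gene Pglym78 rose from 52.6 ± 5.11 to 269 ± 130 CPM (2.35 ± 0.37, adjusted p = 0.0332), as did the NAD kinase gene Nadk2 (2.59 ± 0.42, adjusted p = 0.0332) and CG32243 (1.76 ± 0.19, adjusted p = 0.00341). Of 14 heterochromatin protein genes, 53 chromosome 4 genes and 23 pericentromeric genes, 0 passed edgeR, also adjusted over the list alone. Of 279 pericentromeric genes by position 0 rose and 3 fell, with 4 lower adjusted over the list alone. By camera, gap genes (median -0.55, adjusted p = 0.0122) and neural genes (-0.42, adjusted p = 0.00972) were lower and ribosomal protein genes (0.26, adjusted p = 3.74e-07) higher. Each had adjusted p = 0.83 with an estimated correlation, with 1 neural gene lower adjusted over the list alone and 0 in the others. The count of 41 became 7 without wm4h replicate 1, 222 without wm4h replicate 2, 5 without Su(var)3-9 replicate 1 and 1 without Su(var)3-9 replicate 2. Of 21 named genes past the threshold, CG32243 alone kept its call with each of these libraries left out.

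The 2 Jasper alleles shared changes and also differed at NC14. The receptor gene mthl8 was at 14 ± 2.17 CPM in Su113, at least 300-fold higher than in Su140, where it had 0 counts (adjusted p = 0.00167). CG10962 was lower in Su113 than in Su140 (0.132 ± 0.0141 against 23 ± 2.32 CPM, log2 fold change -7.42 ± 0.55, adjusted p = 0.000193). So was CCHa1-R (-8.10 ± 1.45, adjusted p = 0.02), and Rab26 was higher (6.67 ± 1.18, adjusted p = 0.0194). In the direct comparison 382 genes passed, 292 higher and 90 lower in Su113. The count became 32 without Su113 replicate 1, 22 without Su113 replicate 2, 16 without Su140 replicate 1, and 32 without Su140 replicate 2. It was 39 with the later-zygotic score. Among 10 named genes the calls of CG10962 and mthl8 held with each library left out. Against wm4h, 78 genes changed the same way in both alleles (30 higher, 48 lower), where independent lists would share 1.42 and 4.51. The shared control libraries can raise this count too. Simulated groups without any effect shared at most 0, but such comparisons call few or no genes, so this does not measure their part. Among them were Dscam2, Tsp26A, CG6567 and Smyd4-1. Across genes, which are not independent replicates, the log2 fold changes of the alleles correlated with r = 0.525, against a mean of 0.516 in the simulations. Their covariance was 1 against 0.411, so part of the likeness may come from the shared controls. The count of 78 became 29 without wm4h replicate 1, 194 without wm4h replicate 2, 6 and 14 without the first and second Su113 library, and 33 and 36 without those of Su140.

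In Su113 at St7-8, some transcripts that mothers load into the egg were higher. The thioredoxin gene dhd, which acts at fertilization, rose from 30.2 ± 4.71 to 576 ± 377 CPM (log2 fold change 4.25 ± 0.63, adjusted p = 0.00615). The gene exu, which localizes bicoid RNA, rose from 11.3 ± 2.62 to 151 ± 64.1 (3.73 ± 0.34, adjusted p = 0.000545). The meiotic regulator cort (3.07 ± 0.46, adjusted p = 0.00633) and the kinase gene png of the egg-to-embryo transition (1.80 ± 0.35, adjusted p = 0.0229) also rose. Of 16 maternal germ plasm and meiosis genes 5 rose and 0 fell, with 7 higher adjusted over the list alone (camera adjusted p = 0.000294, and adjusted p = 0.83 with an estimated correlation). The maternal transcript bcd was not among them, at 85.7 and 131 CPM in the Su113 libraries and 116 and 237 in wm4h. Of 15 heat shock genes 2 rose, Hsp26 (2.03 ± 0.48, adjusted p = 0.0459) and Hsp70Bb (3.48 ± 0.73, adjusted p = 0.0279), with 10 adjusted over the list alone (camera adjusted p = 0.000294, and adjusted p = 0.83 with an estimated correlation). Of 25 piRNA genes 4 rose, shu among them (2.03 ± 0.33), and 2 fell, mael (-1.51 ± 0.19) and nxf2 (-1.58 ± 0.24). The counts were 5 and 2 adjusted over the list alone. The glycolytic gene Gapdh2 rose from 26.6 ± 5.42 to 259 ± 146 CPM (3.28 ± 0.38, adjusted p = 0.00172). The detoxification genes GstD1 (4.4 ± 0.35, adjusted p = 0.000231) and Cyp6a19 (5.71 ± 0.72, adjusted p = 0.00286) rose among 4 higher and 2 lower of 108 P450 and transferase genes (7 and 3 adjusted over the list alone).

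Further lists of Su113 at St7-8 passed camera, with few or no members past the edgeR test. Neural genes were lower (median -0.72, adjusted p = 0.000559), with l(1)sc past the threshold (-1.15 ± 0.28, adjusted p = 0.0497) and 5 of 17 adjusted over the list alone. The interband chromatin list was lower (-0.40, adjusted p = 0.00915), with Chro, a chromodomain protein of interbands, past it (-0.60 ± 0.14, adjusted p = 0.0497) and 2 of 12 adjusted over the list alone. Heterochromatin protein (median -0.32, adjusted p = 0.0161), pair-rule (-0.46, adjusted p = 0.0315), dorsal ectoderm (-0.64, adjusted p = 0.0246), cellularization (-0.74, adjusted p = 0.0246) and small RNA genes (-0.47, adjusted p = 0.00972) were lower too. They had 0, 1, 2, 0 and 1 members lower adjusted over the list alone. Markers of older embryos had a median of 4.85 with 0 of 13 past edgeR (camera adjusted p = 0.0191). All these lists had adjusted p = 0.83 with an estimated correlation. Muscle myosin heavy chain (Mhc) stood at 86.8 and 447 CPM in the Su113 libraries and at 9.62 and 0.398 in wm4h. The maternal and heat shock genes were thus higher in libraries that also held muscle transcripts. RLE scaling moved the median log2 fold change of all genes from -0.094 to 0.072 and the higher share from 64.9% to 79.6% of the genes past the threshold (74.3% by DESeq2). Lower genes were instead the majority without wm4h replicate 1 (38.2% higher, 107 against 173), wm4h replicate 2 (37%) or Su113 replicate 1 (41.2%). The count of 353 became 27 without wm4h replicate 2, 1487 without Su113 replicate 1, 109 without Su113 replicate 2, and 110 without the second St7-8 libraries. It was 119 with the later-zygotic score and 1 in the fit to St7-8 libraries alone. With each library left out, 15 of 49 named genes kept their call, among them exu, GstD1, Gapdh2 and mael but not dhd, cort, png, shu, nxf2, Cyp6a19, Hsp26, Hsp70Bb, l(1)sc or Chro. Under every alternative run 1 kept it.

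In Su140 at St7-8, the genes with the largest rise included those of blood cells and muscle. The haemocyte gene Hml rose from 1.13 ± 0.918 to 76.8 ± 9.8 CPM (log2 fold change 6.09 ± 1, adjusted p = 0.0163). PPO1, a prophenoloxidase of crystal cells, was at least 174-fold higher than in wm4h, where it had 0 counts (adjusted p = 0.00482). PPO1 also passed at St7-8 in Su113, at 0.16 and 0.53 CPM (adjusted p = 0.0208), and in Su(var)3-9, at 0.452 and 0.261 CPM (adjusted p = 0.00373), against 2.1 and 12.2 CPM in Su140. At NC14 it stood at 0.489 and 0.399 CPM in Su113 and 0.698 and 0.403 in Su(var)3-9. It was at 0.218 and 0.181 in Su140 and at 2 counts in each wm4h library, and did not pass (adjusted p of 0.112 or more). In Su113 and Su(var)3-9 it thus showed no clear rise from NC14 to St7-8. The muscle gene sls rose from 8.24 ± 5.84 to 226 ± 219 CPM (4.78 ± 1.02, adjusted p = 0.048), while Mhc stood at 0.335 CPM in Su140 replicate 1, under both wm4h libraries. Markers of older embryos as a list had a median of 5.02 (camera adjusted p = 0.0263, and adjusted p = 0.83 with an estimated correlation). Hml was the 1 gene of 13 past the threshold, also adjusted over the list alone. The piRNA genes AGO3 (-1.49 ± 0.18, adjusted p = 0.00353) and mael (-1.16 ± 0.19, adjusted p = 0.0163) fell. They were 2 of 25 with 0 higher, and 6 were lower adjusted over the list alone (camera adjusted p = 0.000272, and adjusted p = 0.83 with an estimated correlation). Hsp23 (-2.48 ± 0.34), mthl8 (at least 419-fold lower, adjusted p = 0.00189), Dscam2 (-4.11 ± 0.40) and mav (-1.31 ± 0.22) fell as they had at NC14. Hox genes (median 0.49, adjusted p = 0.00635), segment polarity (0.38, adjusted p = 0.0122) and Enhancer of split genes (1.13, adjusted p = 0.0053) were higher by camera, with 3, 0 and 0 higher adjusted over the list alone and 0 past edgeR over all genes. Heterochromatin protein genes were lower (-0.30, adjusted p = 0.00972) with 0 past either. All 4 had adjusted p = 0.83 with an estimated correlation.

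In the same comparison, genes on arm 3R that passed were mostly lower, with 3 higher and 32 lower, or 8.6% higher against 40.7% elsewhere (Fisher's exact test with genes taken as independent, adjusted p = 0.00589 over 36 tests). Of 279 pericentromeric genes by position 1 rose and 10 fell, with 3 and 15 adjusted over the list alone (camera adjusted p = 0.028, and adjusted p = 0.83 with an estimated correlation). RLE scaling moved the median of all genes from -0.055 to 0.085 and the higher share from 32.9% to 45.2%, and DESeq2 gave 69.2% and no filter 58.8%. The share was 70.5% without Su140 replicate 1, 12.8% without wm4h replicate 1, 0% without wm4h replicate 2 and 15.6% without Su140 replicate 2. The count of 143 became 20 without wm4h replicate 2, 407 without Su140 replicate 1, 32 without Su140 replicate 2, and 29 without the second St7-8 libraries. It was 34 with the later-zygotic score. In the fit to the St7-8 libraries alone it became 0 by edgeR, while DESeq2 on all libraries gave 986. Of 39 named genes 13 kept their call with each library left out, among them mthl8, Dscam2 and AGO3 but not Hml, PPO1, sls, mael, Hsp23 or mav. Under every alternative run 0 kept it, as the fit to St7-8 libraries alone gave 0 genes.

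In Su(var)3-9 at St7-8, the genes with the largest falls included some of cellularization, and most members of the maternal germ plasm list fell. The genes nullo, bnk and slam act in the furrows that divide the syncytial embryo into cells. The level of nullo fell from 103 ± 56.7 to 0.473 ± 0.269 CPM (log2 fold change -7.73 ± 0.73, adjusted p = 0.000185) and that of bnk from 337 ± 272 to 1.81 ± 0.754 (-7.55 ± 0.63, adjusted p = 0.000169). That of slam fell from 2610 ± 1900 to 32.1 ± 0.248 CPM (-6.35 ± 0.54, adjusted p = 0.000169). Of 10 cellularization and gastrulation genes 4 fell and 1 rose, with 4 and 2 adjusted over the list alone. The list did not pass camera (adjusted p = 0.437, median -0.04, mean -2.14). Of 16 maternal germ plasm and meiosis genes 13 fell and 1 rose, with 14 and 2 adjusted over the list alone (camera adjusted p = 0.000294, and adjusted p = 0.83 with an estimated correlation). Among those that fell were the anterior determinant bcd (-4.31 ± 0.67, adjusted p = 0.00128) and smg, which clears maternal RNA (-2.85 ± 0.43, adjusted p = 0.00104). Of 25 piRNA genes 15 fell and 0 rose, with 17 lower adjusted over the list alone (camera adjusted p = 8.13e-05, and adjusted p = 0.83 with an estimated correlation). Of these mael stood at -3.03 ± 0.20 and BoYb at -1.92 ± 0.23. Of 7 gap genes 4 fell, also adjusted over the list alone (camera adjusted p = 0.0575), among them hb (-2.10 ± 0.27), tll (-1.57 ± 0.35) and gt (-1.49 ± 0.33). Some genes that pattern later embryos rose. Of 8 Hox genes 3 rose (abd-A at 1.75 ± 0.35, Scr at 1.52 ± 0.36, Abd-B at 1.3 ± 0.35). So did 4 of 9 segment polarity genes (gsb at 1.87 ± 0.51, mid at 1.83 ± 0.48, en at 1.73 ± 0.46) and 3 of 11 Enhancer of split genes. The numbers were 8, 6 and 3 adjusted over the list alone. By camera their adjusted p was 0.000954, 0.00366 and 0.00253, each with adjusted p = 0.83 with an estimated correlation.

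Among chromatin genes of Su(var)3-9 at St7-8, a part of each list fell. Of 14 heterochromatin protein genes 4 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.179). Among them were HP5 (-1.86 ± 0.20, adjusted p = 0.000303), Su(var)3-7 (-0.94 ± 0.18) and Su(var)2-HP2 (-0.60 ± 0.14). Of 12 JASPer and interband chromatin genes 4 fell and 1 rose, as also adjusted over the list alone (camera adjusted p = 0.351). Among those that fell were JIL-1, the insulator gene Cp190 (-0.94 ± 0.19) and the histone methyltransferase gene Set2 (-1.82 ± 0.23). Of the X-linked genes past the threshold 123 were higher and 418 lower, or 22.7% higher against 38.8% elsewhere (Fisher's exact test with genes taken as independent, adjusted p = 1.57e-11 over 36 tests). On chromosome 4 the counts were 26 and 17 (60.5% against 35.6%, adjusted p = 0.0104). The 2 wm4h libraries differed in these genes, with slam at 1270 and 3950 CPM against 31.9 and 32.3 in Su(var)3-9, and bnk at 145 and 530 against 2.35 and 1.28. The count of 3080 became 949 without wm4h replicate 2, 1637 without Su(var)3-9 replicate 1, 1509 without Su(var)3-9 replicate 2, and 1606 without the second St7-8 libraries. It was 1399 in the fit to St7-8 libraries alone and 43 with the later-zygotic score. Of 94 named genes 59 kept their call with each library left out, among them nullo, bnk, slam, bcd, smg, mael, BoYb, hb, HP5, Su(var)3-7, Set2 and abd-A, and 20 kept it under every alternative run. The calls of tll, gt, Scr, Abd-B, gsb, mid, en, Cp190, JIL-1 and Su(var)2-HP2 did not hold.

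Between the Jasper alleles at St7-8, the haemocyte gene Hml was lower in Su113 (0.403 ± 0.248 against 76.8 ± 9.8 CPM, log2 fold change -7.51 ± 1.08, adjusted p = 0.00557). Cyp6a19 was higher (55.1 ± 31.5 against 1.35 ± 1.19 CPM, 5.35 ± 0.71, adjusted p = 0.00458). The receptor gene mthl8 was at least 174-fold higher in Su113 (adjusted p = 0.0025) and CG10962 lower (-4.90 ± 0.49, adjusted p = 0.00117), as at NC14. In all, 229 genes were higher and 68 lower in Su113, or 77.1% higher, against 58.8% by DESeq2. The excess of higher genes was nearly gone without Su113 replicate 1. The count became 1450 without Su113 replicate 1, 65 without Su113 replicate 2, 126 without Su140 replicate 1, 109 without Su140 replicate 2, and 158 without the second St7-8 libraries. It was 4 with the later-zygotic score. In the fit to the St7-8 libraries alone it was 0 by edgeR, with 2290 genes at an unadjusted p under 0.05 on all libraries and 1409 past DESeq2. Of 10 named genes 6 kept their call with each library left out, CG10962, Cyp6a19 and mthl8 among them but not Hml, and 0 kept it under every alternative run. Against wm4h, 50 genes changed the same way in both alleles (19 higher, 31 lower). Among them were Dscam2, Tsp26A, CG6567 and Cyp6d4. Independent lists would share 0.868 and 0.96. Across genes r was 0.766 against a simulated mean of 0.499, and the covariance 2.09 against 0.438. The count of 50 became 5 without wm4h replicate 2, 166 without Su140 replicate 1, 13 without Su140 replicate 2 and 8 without the second St7-8 libraries.

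Mutants of the different genes also shared changes. At NC14 Su113 and Su(var)3-9 changed 17 genes the same way, where independent lists would share 0.0682 higher and 0.128 lower. Su140 and Su(var)3-9 changed 23 (0.544 and 1.5). At St7-8 the count was 76 for Su113 and Su(var)3-9, where independent lists would share 20.5 higher and 19.7 lower, with another 52 in opposite directions. It was 70 for Su140 and Su(var)3-9 (4.2 and 15.3), with another 3 in opposite directions. Across genes, r for the same pairs was 0.537 and 0.409 at NC14, against simulated means of 0.522 and 0.517 without any effect. At St7-8 it was 0.224 and 0.322, below the simulated 0.498 and 0.497. The covariance lay above the simulated mean for each pair. At NC14 it was 0.836 and 0.725, against 0.415 and 0.414. At St7-8 the covariance was 0.614 and 0.849, against 0.435 and 0.433. The lower r at St7-8 thus does not mean less shared change than without any effect. At NC14, 14 genes changed the same way in all 3 mutants, among them Dscam2, CG6567, pyd3, Cap-H2, CanB, Pex19, Smyd4-1 and snRNA:U2:34ABa. At St7-8 there were 26 such genes, and 7 were in both sets. All these counts share their control libraries, which can raise them. Simulated groups without any effect shared at most 0 at NC14 and 1 at St7-8, which again does not measure their part.

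Between NC14 and St7-8 in wm4h, 0 genes passed the edgeR test, with 1395 at an unadjusted p under 0.05 and a smallest adjusted p of 0.324. There were 462 genes past DESeq2. Adjusted over the list alone, 3 of 7 gap genes and 3 of 9 pair-rule genes were lower at St7-8 and 3 of 11 Enhancer of split genes were higher. The count became 186 without wm4h NC14 replicate 2 and 263 without the second St7-8 libraries of wm4h, Su113 and Su140 together. It was 0 by edgeR without wm4h St7-8 replicate 2 alone, as without wm4h NC14 replicate 1 or wm4h St7-8 replicate 1. The later-zygotic score of wm4h St7-8 replicate 2 (3.57) lay closer to those of the NC14 libraries (3.33 and 3.39) than to that of replicate 1 (4.39).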

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

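All tests of explanations here were chosen after the results were seen, while the tests of a difference between the stages were planned.

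The effect of each mutation was compared between NC14 and St7-8, and genes whose effect differed between the stages are listed here as a difference between groups. There were 11 such genes in Su113 (11 higher at St7-8 relative to NC14), 34 in Su140 (30 higher, 4 lower) and 228 in Su(var)3-9 (12 higher, 216 lower). For Su113 the differences of log2 fold change were 4.16 for D19A, 4.69 for CG3902, 4.92 for GstD1, 5.44 for dhd and 6.27 for Cyp6a19. The effect on dhd was -1.19 at NC14 and 4.25 at St7-8, and that on GstD1 was -0.52 and 4.4. For Su140 they were -1.99 for Gmer, -1.45 for CG32243, -1.41 for Dph1, -1.32 for CG8520. They were 4.48 for CG13300, 4.53 for the unmatched identifier FBgn0040813, 4.55 for caup, 4.65 for so and 4.86 for apolpp, a lipid carrier. The effect on so, an eye and head regulator, was -4.14 at NC14 and 0.51 at St7-8. For Su(var)3-9 they were -7.55 for CG13716, -7.17 for nullo, -7.11 for CG18269, -6.62 for CG15382, -6.56 for bnk. They were 1.74 for Polr3A, 1.78 for the unmatched identifier FBgn0001981, 1.84 for Fancm, 2.44 for CG3829 and 3.46 for mth. The effect on nullo was -0.56 at NC14 and -7.73 at St7-8, and that on mth was -3.9 and -0.44.

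These counts rested on single libraries, and so did the balance of directions in Su140. Without wm4h St7-8 replicate 1, lower genes were the majority there. Leaving out a wm4h NC14 library changed the Su113 count to 2 and 53, a wm4h St7-8 library to 3 and 0, for replicates 1 and 2 in turn. A Su113 NC14 library changed it to 0 and 2, and a Su113 St7-8 library to 653 and 7. The Su140 count became 1 and 6, 2028 and 0, 0 and 0, and 471 and 2 in the same order of groups, with Su140 in place of Su113. The Su(var)3-9 count became 10 and 74, 1083 and 71, 15 and 423, and 149 and 11. Beside the counts of 0 by edgeR, 2204 and 3392 genes had an unadjusted p under 0.05 for Su113 and Su140 on all libraries, and DESeq2 gave 812 and 1895. The named calls that held with each library left out were those of bnk and CG15382 in Su(var)3-9.

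In Su140 at NC14, part of the Hox, segment polarity and pair-rule genes were lower. In Su(var)3-9 at St7-8, part of the maternal germ plasm genes and 4 of 10 cellularization genes were lower, and part of the Hox genes higher. Groups of embryos that differ in age would give such changes. None of these lists passed camera with an estimated correlation. For Su140 the tables argued against library depth, since the mean totals of Su140 and wm4h stood at a ratio of 1. For Su(var)3-9, the highest later-zygotic score of wm4h at NC14 minus that at St7-8 was -1. This argued against an exchange of a wm4h NC14 library with wm4h St7-8 replicate 1, which scored 4.39. Replicate 2 scored 3.57, against 3.33 and 3.39 at NC14. An exchange with it would hardly move the difference and could not be excluded. Of 374 Su140 genes that also changed between the Su(var)3-9 stages, 287 (76.7%) went against the stage direction, a value between the bounds of 60 and 80% set for the test, so younger Su140 embryos stayed open. Of 969 Su(var)3-9 genes that differed at least 2-fold between Su140 St7-8 replicate 1 and Su140 NC14, 935 (96.5%) went in the stage direction. Younger wm4h St7-8 embryos or older Su(var)3-9 embryos would give this. An effect of the mutations on the pace of development would give the same values and cannot be told apart from the age of the sorted embryos in this design. It would not make the wm4h St7-8 libraries differ from each other. Replicate 2 of these had slam at 3950 and bnk at 530 CPM, against 1270 and 145 in replicate 1. The wm4h NC14 libraries had slam at 2650 and 3700 and bnk at 478 and 383 CPM. Part of the Su(var)3-9 pattern at St7-8 may thus come from the control libraries. Against the other mutants at St7-8 Su(var)3-9 stood apart too. There slam stood at 1760 and 955 CPM in Su113 and 2410 and 1920 in Su140, against 31.9 and 32.3 in Su(var)3-9. In the same order bnk stood at 170 and 128, 234 and 213, and 2.35 and 1.28 CPM. The later-zygotic scores of Su(var)3-9 at St7-8, 5.52 and 5.37, were also above those of Su113 (3.91 and 2.55) and Su140 (4.94 and 4.93). The control libraries alone thus do not give the low slam and bnk of Su(var)3-9.

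At St7-8 the muscle gene sls stood at 71.2 and 381 CPM in Su140, 97.1 and 222 in Su113, 52 and 6.74 in Su(var)3-9 and 12.4 and 4.11 in wm4h, in the same order the haemocyte gene Hml at 83.7 and 69.9, 0.578 and 0.227, 50.5 and 9.96, and 0.478 and 1.78, and the oocyte gene dhd at 54.8 and 16, 309 and 842, 7.81 and 9.47, and 33.5 and 26.9, while Mhc in Su140 replicate 1 was at 0.335 CPM, under both wm4h libraries. The tables argued against ovary or adult female tissue, whose yolk protein and eggshell genes reached at most 0.814 CPM (Yp3) in the Su113 and Su140 St7-8 libraries, against 1.22 CPM for Yp3 in a Su(var)3-9 St7-8 library. In Su140, 11 of 13 markers of older embryos were higher in replicate 2 than in replicate 1, with a median difference of 5.98 on the log2 scale, so a few older embryos in that pool may have contributed, although Hml was high in both libraries, and the haemocyte gene PPO1 stood at 2.1 and 12.2 CPM in Su140, 0.16 and 0.53 in Su113 and 0 in wm4h. Maternal germ plasm genes in Su113 stood at a mean log2 CPM of 6.46 and 7.34 at St7-8 and at 5.24 and 5.42 at NC14, while bcd stood at 85.7 and 131 CPM against 116 and 237 in wm4h. In Su113 at St7-8, 10 of 13 markers of older embryos had a positive log2 fold change (median 4.85), with 0 past edgeR. Mhc stood there at 86.8 and 447 CPM, against 9.62 and 0.398 in wm4h, while Hml did not share this rise. The muscle signal was thus not particular to Su140. Older embryos in the Su113 pools were not tested and stay open. So do unfertilized eggs or arrested embryos in these pools and an effect of the mutation on RNA clearance, which were not tested either.

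At NC14, 14 genes changed the same way in all 3 mutants, where independent lists would share 0.0104, and 78 did so in both Jasper alleles. The tables argued against chance values of the wm4h NC14 libraries for the 14 genes, since all 14 had the same direction in all 3 mutants at St7-8, against other wm4h libraries (one-sided exact binomial p = 6.1e-05 with genes taken as independent), and 7 passed there in all 3. Of the 78, 29.5% (exact 95% interval 19.7 to 40.9) lay on the chromosome of Jasper (arms 3L and 3R), against 44% of the tested genes. This argued against linked sequence that changes genes of its own chromosome as the cause of most of them, although part could still be linked. Linked sequence that acts on genes of any chromosome would not raise this share, so the test cannot exclude it. A strain difference of the wm4h stock would give the same direction at both stages, and so would shared effects of the mutations, and neither could be excluded. The silence of mthl8 in Su140 (0 counts at both stages, against 14 ± 2.17 CPM in Su113 at NC14) differs between the alleles of 1 gene, and a sequence difference at its locus was not tested.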

How the results depend on the processing

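The later-zygotic covariate and the omission of the second St7-8 libraries were chosen after the data were seen, and the other alternatives were planned. The numbers here count each named gene once per comparison in which it was named. Under RLE scaling 375 kept their side of the threshold, with the same direction where past it, and 11 lost the call. The corresponding numbers were 381 and 3 with DESeq2 (1 gained it), 378 and 7 without a filter (1 gained it), and 337 and 49 with the block. They were 246 and 139 with fewer libraries (1 gained it), 138 and 63 without the second St7-8 libraries, and 156 and 202 with the covariate. Over the fits with 1 library left out, counted once per fit, they were 995 and 644 (1 gained it). With the covariate, 4 values reversed, to 0.17 for stumps and 0.02 for run in Su140 at NC14 and to -0.01 for slp1 and -0.02 for Abd-B in Su(var)3-9 at St7-8. The score is made of genes that include Abd-B, and it varies with the groups, so the covariate removes part of any effect that goes with it. The causes of the other changes were not tested. Fits to fewer libraries have fewer samples. With the libraries of 1 stage alone, however, the mutant and allele counts rose at NC14 and fell at St7-8. Replicates differed more at St7-8 (SD of the log2 CPM difference 0.92 to 1.55) than at NC14 (0.57 to 0.85). A fit to 1 stage does not share the spread between the stages, as the main fit does.

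In the order of mutant comparison at NC14 (Su113, Su140, Su(var)3-9), allele difference at NC14, the same 4 at St7-8, stage change of wm4h, stage dependence (Su113, Su140, Su(var)3-9) and both alleles (NC14, St7-8), the counts are given here where they moved by 1.5 times or more. Under RLE they stayed within 1.5 times apart from stage dependence of Su113 (25) and Su140 (151), and without a filter apart from stage dependence (39, 250 and 378). With the block, those that moved were 72 (Su113), 20 (Su(var)3-9) and 213 (alleles) at NC14, 230 (Su113) and 81 (Su140) at St7-8, 4 and 1 (stage dependence of Su113 and Su140), and 49 and 31 (both alleles). DESeq2 gave 794, 2565, 798 and 1777 at NC14 and 1392, 986 and 1409 at St7-8 for Su113, Su140 and the alleles. It gave 462 for the stage change, 812, 1895 and 1053 for stage dependence, and 451 and 4.1e2 (to 2 digits) for both alleles. Su(var)3-9 at St7-8 stayed within 1.5 times. It kept 97% or more of the genes in each mutant comparison. With the libraries compared or of the same stage alone, the counts were 392, 2426, 357 and 1675 at NC14, and 1, 0, 1399 and 0 at St7-8. They were 3 for the stage change, 15 and 20 for stage dependence of Su140 and Su(var)3-9, and 253 and 0 for both alleles. For these counts of 0 from edgeR, those at an unadjusted p under 0.05 on all libraries were 2273 (Su140) and 2290 (alleles). Without the second St7-8 libraries they were 110, 29, 1606 and 158 at St7-8, 263 for the stage change and 8 for both alleles. With the covariate they were 200, 23 and 39 at NC14 (Su113, Su140 and alleles), 119, 34, 43 and 4 at St7-8, 4 for the stage change, and 16 and 11 for both alleles.

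Leaving out 1 library in turn gave ranges of 6 to 272 (Su113), 124 to 782 (Su140), 1 to 222 (Su(var)3-9) and 16 to 32 (alleles) at NC14. At St7-8 they were 27 to 1487, 20 to 407, 949 to 3523 and 65 to 1450. They were 0 to 186 for the stage change, 0 to 653, 0 to 2028 and 10 to 1083 for stage dependence, and 6 to 194 and 5 to 166 for both alleles. The list tests gave 47 pairs past the threshold by the preset correlation, 49 to 54 under the scaling, filter and block alternatives, 42 to 62 with a library left out, and 0 with an estimated correlation, where the smallest adjusted p was 0.83. Depth limits statements on genes near the floor of 0.0299 to 0.0573 CPM.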

Other observations

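The Fisher tests of direction by chromosome arm took genes as independent and were chosen after the results were seen, and the other tests used here were planned.

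Further gene groups changed in part in Su(var)3-9 at St7-8. Of 16 dorsal ectoderm and amnioserosa genes 2 rose and 4 fell, with 5 and 5 adjusted over the list alone (camera adjusted p = 0.725), among them scw, a ligand of dorsal fates (log2 fold change -5.06 ± 0.49, adjusted p = 0.000204), and zen, a homeobox gene of the amnioserosa (-2.53 ± 0.41, adjusted p = 0.0016). The list's median was 0.89 and its mean -0.1. Of 9 pair-rule genes slp2 rose (1.4 ± 0.38) with 1 other and eve fell (-1.64 ± 0.44), with the same counts adjusted over the list alone. Of 9 mesoderm genes 1 rose, Mef2, a regulator of muscle genes (1.1 ± 0.31, adjusted p = 0.0214), also adjusted over the list alone (camera adjusted p = 0.0328, and adjusted p = 0.83 with an estimated correlation). Of 17 neural genes 1 rose and 2 fell, with 0 and 2 adjusted over the list alone, and none of 8 endoderm genes passed edgeR in either way. Of 15 heat shock genes 1 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.178), among them Hsp27 (-2.73 ± 0.52, adjusted p = 0.00358). Of 108 P450 and transferase genes 6 rose and 19 fell, also adjusted over the list alone (camera adjusted p = 0.651), with Cyp6d4 at -3.46 ± 0.41. The haemocyte gene Hml rose (4.74 ± 0.94, adjusted p = 0.00446) as the 1 gene of 13 markers of older embryos, also adjusted over the list alone (list median -0.46, camera adjusted p = 0.972). The calls of scw, zen, Hsp27, Cyp6d4 and Hml held with each library left out, and that of Mef2 ended without wm4h replicate 2 or either Su(var)3-9 library.

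Sex determination and dosage compensation were also measured there. Of 10 X-counting genes 1 rose and 3 fell, also adjusted over the list alone, among the latter dpn (-1.44 ± 0.3, adjusted p = 0.00555), which ended without wm4h St7-8 replicate 2. Of 7 dosage compensation genes 1 rose and 2 fell, also adjusted over the list alone. Those were the male-specific roX2 RNA gene (2.79 ± 0.62, adjusted p = 0.00765), msl-1 (-0.99 ± 0.2) and mof (-0.74 ± 0.22). In Su113 at St7-8 roX2 rose as well (3.28 ± 0.63), as 1 of 7, also adjusted over the list alone. The call of roX2 ended without wm4h St7-8 replicate 2 in both mutants (adjusted p = 0.0812 in Su(var)3-9 and 0.18 in Su113), and in Su113 also without wm4h St7-8 replicate 1 or Su113 St7-8 replicate 2. In Su140 at NC14, 2 of 10 X-counting genes fell, da (-0.7 ± 0.19) and run (-1.16 ± 0.31), also adjusted over the list alone, and 0 of 7 dosage compensation genes passed edgeR, with 1 lower adjusted over the list alone. None of 27 genes of the Y chromosome passed edgeR in the 6 mutant comparisons. The sex of the pooled embryos is not given in the labels.

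Near the genes under study, eIF2gamma, which shares its span with Su(var)3-9, rose in Su(var)3-9 at St7-8 (1.01 ± 0.16, adjusted p = 0.0016) and kept its call with each library left out. Over all 12398 genes tested, 1108 were higher and 1972 lower in that comparison, so the counts near single genes do not by themselves show an effect of position. Within 500 kb of Su(var)3-9, 10 of 108 genes were higher there and 14 lower, with 9 and 13 adjusted over the list alone. Within 500 kb of Jasper 11 of 146 were higher and 13 lower, with 7 and 12 adjusted over the list alone, and within 500 kb of w 3 of 69 were higher and 13 lower, with the same counts adjusted over the list alone. Of 15 genes flanking w, 0 were higher and 2 lower, dnc (-2.51 ± 0.38) and z (-0.55 ± 0.16), also adjusted over the list alone. In Su140 at NC14 the counts were 2 and 8 near Jasper (0 and 6 adjusted over the list alone), 5 and 2 near w, and 3 and 1 in the flanking list, the latter pair also adjusted over the list alone. Over all genes tested, 375 were higher and 810 lower in that comparison. No gene of the 146 near Jasper passed edgeR in Su113 at NC14, where 116 of all 12398 genes did. Of 53 chromosome 4 genes 14 rose and 11 fell in Su(var)3-9 at St7-8 (15 and 12 adjusted over the list alone), and of 23 pericentromeric genes 0 rose and 4 fell (0 and 3). Of 279 pericentromeric genes by position 14 rose and 50 fell (13 and 48). None of these 3 lists passed camera, with adjusted p of 0.265, 0.972 and 0.666.

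Ribosomal protein genes had a median of 0.2 in Su140 at NC14 (camera adjusted p = 0.000294), -0.28 in Su113 at St7-8 (1.45e-06) and -0.27 in Su140 at St7-8 (7.8e-07), with at most 3 of 91 past edgeR and adjusted p = 0.83 with an estimated correlation in each. At St7-8 RLE scaling moved the median of all genes from -0.094 to 0.072 in Su113 and from -0.055 to 0.085 in Su140, so the sizes at St7-8 depend in part on the scaling. Of 242 small nuclear and nucleolar RNA genes 12 rose and 6 fell in Su(var)3-9 at St7-8, with 4 and 6 adjusted over the list alone (median 0.52, camera adjusted p = 0.00366, and adjusted p = 0.83 with an estimated correlation). Of 4 histone genes 1 rose in Su140 at NC14, 1 rose in Su(var)3-9 at St7-8 and 1 fell in Su113 at St7-8, in a multi-copy family. Adjusted over the list alone, 1 was higher in each of these and 1 lower in Su113. None of 4 immune genes and none of 7 markers of ovary and adult tissue passed edgeR in the 6 mutant comparisons, also adjusted over the list alone. By arm, genes of 3R past the threshold in Su140 at NC14 were 24.6% higher against 34% elsewhere (Fisher's exact test, adjusted p = 0.0183) and those of 2L 39.9% against 29.9% (0.0374), and X-linked genes in Su113 at St7-8 85.2% against 61.2% (0.00672).

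In the principal component analysis, the first component held 40.7% of the variance and the second 20.4%, and the 2 wm4h St7-8 libraries lay at 33.3 and -42.8 on the first. Other St7-8 pairs also lay apart on it, at 88.9 and 140 in Su113, 18.3 and 153.7 in Su140, and 41.8 and -6.7 in Su(var)3-9. The later-zygotic score was 3.91 in Su113 St7-8 replicate 1 and 2.55 in replicate 2. Replicate libraries correlated across genes, which are not independent replicates, with r of 0.93 to 0.992 in log2 CPM.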
